A study of Homo sapiens with 10 samples.

How the data were processed

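The series used long-read sequencing of polyadenylated RNA to read the marks that Ribo-STAMP leaves on messenger RNA. In Ribo-STAMP the cytidine deaminase APOBEC1 is fused to RPS2, a protein of the small ribosomal subunit, so that mRNA on ribosomes collects C-to-U edits. The unfused deaminase (APOBEC1-only) gives the background of the editor. Per the labels' protocols, the constructs were induced with 1 ug/mL doxycycline, for 72 h in HEK293T and 48 h in MDA-MB-231, and treated MDA-MB-231 cells received 100 uM CoCl2 for 48 h. The library preparation kits and the induction times differed between the cell lines, per the labels' protocols, so no test was made between the lines. The 10 libraries were grouped by their labels into HEK293T APOBEC1-only (n = 3), HEK293T Ribo-STAMP (n = 3), MDA-MB-231 untreated (n = 2) and MDA-MB-231 CoCl2 (n = 2). The labels number the replicates but do not say that they came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

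The authors deposited 1 text file per library, in which each cell holds a pair of whole-number read counts, the edited reads and the coverage, for a coding-sequence position in an annotated isoform. This reading of the cells comes from the values, since the files have no header: the first number never exceeded the second, and the second was nearly constant along an isoform. Only positions with at least 1 edited read are listed. The aligner, the edit caller, its filters and the counting by strand are not given in the sources used here. Genome builds hg19 and hg38 are named per the submitters' processing notes, without saying which file used which. In the MDA-MB-231 files 99.8 to 99.9% of entries lay inside the GRCh38 coding sequence of their own gene (GENCODE 29), and in the HEK293T files 2.35 to 4.72% did. GRCh38 coordinates are therefore given only for MDA-MB-231, no coordinate was converted, and sequence context and place along the coding sequence were computed only there. No position was listed in all 6 HEK293T libraries (54 were in 5) or in all 4 MDA-MB-231 libraries (39893 were in 3). No source used here says which step left such positions out.

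The depth of a whole library is not known from these files, and the reads on the listed isoforms stand in for it: 81590 to 110537 in APOBEC1-only, 157540 to 203101 in HEK293T Ribo-STAMP and 1120263 to 1204706 in MDA-MB-231. Relative depth was the median ratio of isoform coverage over isoforms listed in every library of a line (405 in HEK293T, 7313 in MDA-MB-231). Edited reads per gene were summed over all positions and isoforms of a gene and divided by relative depth, which keeps a global difference in editing. Coverage per gene was the sum of the median coverage of isoforms listed in every library, scaled by a trimmed mean of M-values (TMM, trims of 30 and 5%) and used as a stand-in for mRNA abundance. Editing per covering read used the same isoforms. Edited and unedited reads were summed over the union of positions times the isoform coverage, 0.5 was added to each, and their log2 ratio (a logit) was tested. Levels are shown as edited reads per 100 covering reads, which can pass 100 because edited reads are summed over positions. An isoform enters coverage and editing per read only if it was edited in every library, which in HEK293T selects isoforms edited in APOBEC1-only cells.

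Genes needed at least 10 edited reads in as many libraries as the smaller group has, or a mean coverage of at least 10. Tests per gene used limma 3.58.1 (R 4.3.3) with an intensity trend, on log2(scaled value + 1) or on the logit, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Adding 1 understates the change of genes with few edited reads. A count model and positions called in all libraries were planned. The design kept the count model for files with counts in a column of their own, and here each cell holds 2 numbers, so limma on log values was used, although sums of edited reads are whole numbers. Since no position was in all libraries, shared isoforms took their place. Values per library were compared with exact permutation tests, two-sided, which cannot go below p = 0.1 for 3 against 3 libraries or 0.333 for 2 against 2. Binomial intervals are exact (Clopper-Pearson, 95%) and cover counting error only, since reads need not be independent molecules.

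Gene lists (19, including 2 lists of line markers as a check of the labels) were tested with limma's camera at a preset correlation of 0.01 where at least 5 members were tested, and again with an estimated correlation and with fry. camera compares a list with the other genes. fry tests whether the genes of a list move, on balance, one way, and does not compare the list with other genes. The lists were hypoxia-induced genes, glycolysis, cytosolic ribosomal proteins, translation factors, integrated stress response, unfolded protein response chaperones, cytosolic heat shock, metal and oxidative response, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, tricarboxylic acid cycle, cell cycle, cholesterol and fatty acid synthesis, extracellular matrix, cytoskeleton, proteasome, interferon response, and markers of each line. The heat shock list, although named cytosolic, also holds the mitochondrial chaperones HSPA9, HSPD1 and HSPE1, and chaperonin genes such as TCP1. Named genes followed a fixed rule. RPS2 came first, as part of the construct. APOBEC1 was in none of the tested gene sets. Then came the 10 largest rises and falls past the threshold with groups that did not overlap and a mean of at least 30 edited reads, 30 covering reads or 100 covering reads (editing per read), and up to 4 members of each list with the smallest p. Genes named because a count was 5 or fewer were chosen after their values were seen. A few genes that the rule selects are not reported here. Groups, lists, rule, tests and alternatives were chosen before the data were examined, except those said to have been added.

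Alternatives were other scalings, filters of 0 or 30 reads, the number of edited positions, positions covered by at least 20 reads, positions with under 50% of reads edited, limma-voom, the replicate number as a block, and leaving out each library. Added after seeing the data were other values before the log (0.5 and 4), leaving out both HEK293T libraries numbered 3, and taking the trend with transcript length (GENCODE 29 transcripts, matched by identifier for 96.4 to 97.7% of isoforms) out of each MDA-MB-231 library. The steps were tested on simulated data with up to 200 changed genes. Both HEK293T groups were simulated at the Ribo-STAMP level of editing. Recovery in HEK293T therefore does not describe the real comparison, where APOBEC1-only libraries held far fewer edited reads. At 2-fold and 4-fold, edited reads recovered 6.45 and 59.3% in HEK293T (1203 genes) and 47.9 and 95.8% in MDA-MB-231 (4048 genes). Editing per read recovered 20.5 and 86.6% in HEK293T (392 genes) and 34 and 87% in MDA-MB-231 (5643 genes), and coverage 73.7 and 99.0% (5665 genes). Isoform pairs (419 genes) recovered 78 of 100 and 100 of 100, with 7 of 219 unchanged pairs called. In simulated MDA-MB-231 coverage, lists of 30 genes raised by a log2 of 0.5 were called in 20 of 20 cases and unchanged lists in 0 of 20. The genes were simulated independently and without a length trend, so false calls among correlated genes were not measured. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.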

Results

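Coding-sequence C-to-U edits were measured in 10 long-read libraries of 2 human cell lines. HEK293T, an embryonic kidney line that carries the SV40 large T antigen, expressed APOBEC1 alone (n = 3) or Ribo-STAMP, the RPS2-APOBEC1 fusion (n = 3). MDA-MB-231, a triple-negative breast cancer line, expressed Ribo-STAMP and was left untreated (n = 2) or given CoCl2 (n = 2), a cobalt salt that stabilises hypoxia-inducible factors and so mimics low oxygen. The 3 APOBEC1-only libraries listed 3308, 3019 and 2791 edited positions with 3498, 3173 and 2971 edited reads, and the 3 HEK293T Ribo-STAMP libraries 49078, 39385 and 42763 positions with 65792, 50908 and 59227 edited reads. Untreated MDA-MB-231 libraries listed 134694 and 123376 positions with 177069 and 158721 edited reads, and CoCl2 libraries 125825 and 116253 positions with 172625 and 155572 edited reads. Median coverage of a listed position was 53, 50 and 45 reads in APOBEC1-only, 83, 62 and 60 in HEK293T Ribo-STAMP, 150 and 143 in untreated and 147 and 137 in CoCl2-treated MDA-MB-231 cells.

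The first comparison, meant to benchmark long-read Ribo-STAMP, asked how far fusing the deaminase to the ribosome raised editing over the free enzyme in HEK293T. At matched depth, Ribo-STAMP libraries held 55824 ± 1701 edited reads and APOBEC1-only libraries 3357 ± 239 (SD, n = 3 each), a ratio of 16.6. The median gene carried 35.3 ± 1.73 edited reads per 100 covering reads with Ribo-STAMP and 2.62 ± 0.278 with APOBEC1 alone, a ratio of 13.5. This value used only isoforms edited in every library, which sets a floor under the APOBEC1-only level. Per 1000 reads on listed isoforms, the values were 325 ± 2.58 and 33.1 ± 2.84, although isoforms with no edit are missing from both denominators. Positions with a single edited read made up 83.9 ± 1.04% of Ribo-STAMP and 96.5 ± 0.771% of APOBEC1-only positions. Every Ribo-STAMP library lay on the same side of every APOBEC1-only library in these 4 measures (exact permutation p = 0.1 for each, two-sided, the smallest that 3 against 3 allows). With only positions carrying at least 2 edited reads the ratio of edited reads was 70.2.

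Ribo-STAMP libraries shared more of their positions with each other than APOBEC1-only libraries did. Of the positions of Ribo-STAMP replicates 1, 2 and 3, 30.9, 37.2 and 32.3% were also listed in another Ribo-STAMP library (exact Clopper-Pearson 95% intervals 30.5 to 31.3, 36.7 to 37.7 and 31.8 to 32.7%). For APOBEC1-only these shares were 6.26, 6.36 and 6.27% (5.46 to 7.14, 5.52 to 7.29 and 5.40 to 7.23%). Between 1.95 and 2.25% of Ribo-STAMP positions were also listed in an APOBEC1-only library, and 21.2 to 22.1% of APOBEC1-only positions in a Ribo-STAMP library. Shares were not matched for the number of positions, which was higher in Ribo-STAMP, and positions present in all 6 libraries are absent from the files.

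**Figure D1:**
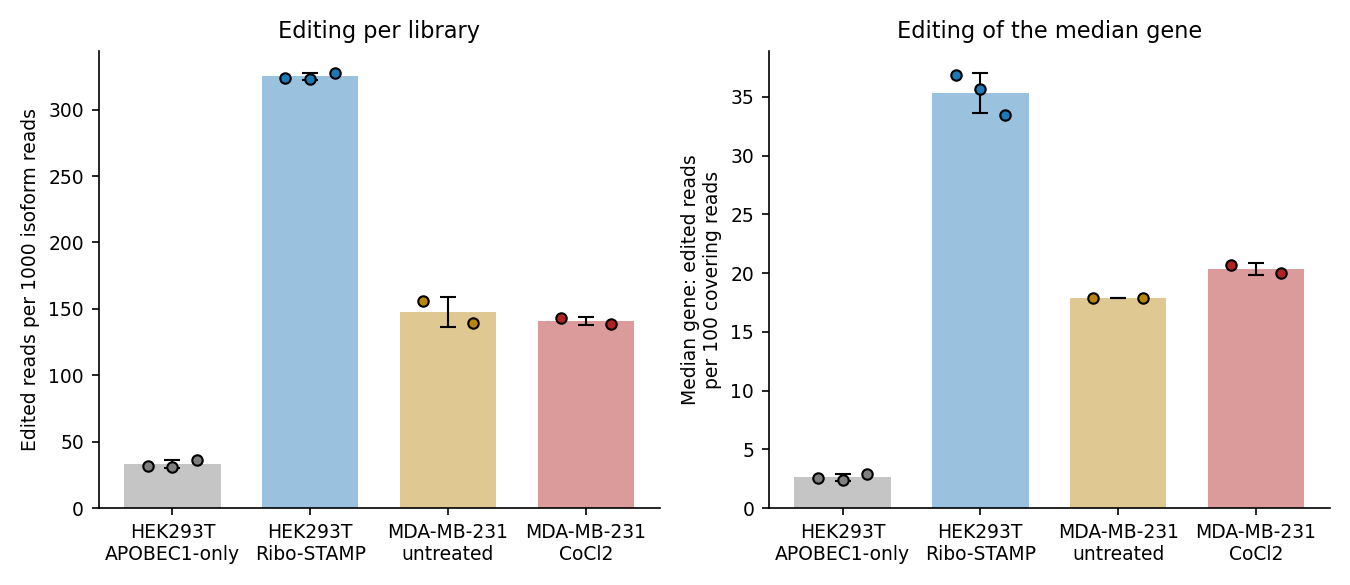
Edited reads per 1000 reads on listed isoforms (left) and edited reads per 100 covering reads of the median gene (right) in each group; bars are means, error bars SD and points single libraries (n = 3 per HEK293T group, n = 2 per MDA-MB-231 group). HEK293T Ribo-STAMP stood at 325 and 35.3 against 33.1 and 2.62 in APOBEC1-only, while the MDA-MB-231 groups lay at 148 and 141 (left) and 17.9 and 20.3 (right); the lines were not compared by a test.

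Edited reads per gene then showed which transcripts carried more edits with the ribosome fusion than with the free enzyme in HEK293T. The levels of the constructs were not measured here, so a higher editor level is not separated from ribosome targeting. RPS2, whose coding sequence is part of the construct, held 176 ± 146 depth-scaled edited reads with Ribo-STAMP and 3.09 ± 3.67 with APOBEC1 alone (log2 change 5.50 ± 0.61 SE, adjusted p = 6.84e-11). The RPS2 values were 84.2, 101 and 344 in Ribo-STAMP replicates 1, 2 and 3 and 0.935, 1.00 and 7.33 in APOBEC1-only, so the libraries numbered 3 carried much of both means. LRPPRC, which binds mitochondrial mRNA, rose most among genes meeting the naming rule, from 2.31 ± 3.23 to 251 ± 87.4 (log2 change 6.67). XPOT, the tRNA exporter, rose from 0.814 ± 1.41 to 102 ± 46.0. RRM1, the large subunit of ribonucleotide reductase, rose from 1.62 ± 1.51 to 120 ± 11.8, and CSE1L, a nuclear export receptor, from 7.5 ± 5.45 to 330 ± 179 (n = 3 each). ALDH18A1, PAPOLA, PLS3, YWHAZ and ENSG00000068793, which has no symbol in the gene names used here, completed the 10 largest rises. Their log2 changes were 5.51 to 5.65. When libraries were scaled to the bulk of genes (TMM), 0 of the genes named by the rule kept their call. None of them was therefore set apart from the general rise.

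Of 654 genes tested with limma, 652 rose and 1 fell, with a median log2 change of 3.76. The fall was PHYH, a peroxisomal hydroxylase named here after its values were seen. It held 11.3 ± 2.40 edited reads in APOBEC1-only and 6.96 ± 11.3 in Ribo-STAMP cells (log2 change -1.83, adjusted p = 0.0102, and 0.000503 to 0.0417 over the alternatives that kept it below the threshold). Its groups overlapped, and its call held in only 1 of the 6 sets that left out a library, the set without Ribo-STAMP replicate 3. It was not called by limma-voom, nor from positions covered by at least 20 reads, positions with under 50% of reads edited, or the number of positions. Leaving out APOBEC1-only replicate 1, 2 or 3 gave 1066, 1064 and 1059 rises among 1086 genes, since the filter then asks for fewer libraries. Under TMM, which centres on the bulk of genes, the median log2 change was 0.75, and 25 genes rose and 1, PHYH, fell. The filter of at least 10 edited reads in 3 libraries could be met by the Ribo-STAMP libraries alone, which favours genes that rose. With no filter beyond 1 edited read, 2267 of 7004 genes rose and 0 fell.

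In HEK293T edited reads 652 of all 654 tested genes rose, a share that the filter favours, so rises within lists do not set a list apart. Every tested list member rose. These were 17 of 17 translation factors, 15 of 15 heat shock genes and 13 of 13 cell cycle genes. They were also 9 of 9 glycolysis genes and 9 of 9 cytoskeleton genes. The same held for 8 of 8 unfolded protein response chaperones, 8 of 8 tricarboxylic acid cycle genes, 5 of 5 ribosomal proteins and 5 of 5 integrated stress response genes. Counts adjusted over the list alone were the same for these 9 lists. The elongation factor EEF1A1 rose from 11.9 ± 5.61 to 635 ± 609 edited reads, and the poly(A)-binding protein PABPC1 from 13.3 ± 11.1 to 320 ± 244. Ribo-STAMP replicate 3 carried much of these means (EEF1A1 195, 380 and 1330, PABPC1 148, 213 and 599 in replicates 1, 2 and 3), and APOBEC1-only replicate 3 was also the highest of its group (18.3 and 25.6). Among chaperones HSP90AB1 rose from 14.1 ± 4.96 to 425 ± 114 and HSP90B1, of the endoplasmic reticulum, from 13.5 ± 4.27 to 471 ± 104. Replication genes included TOP2A, from 11.2 ± 2.22 to 258 ± 72.2, and MCM4, from 9.66 ± 3.49 to 242 ± 80.2. Among lists with fewer than 5 tested members, the log2 changes of PLOD1 (hypoxia, 2.90), TFRC (metal response, 4.69), ACLY (cholesterol and fatty acid synthesis, 5.20) and ITGB1 (extracellular matrix, 3.53) were rises as well. So were those of PSMD1 (proteasome, 4.90) and the line markers NEFM (3.79) and CKB (3.72). Medians ran from 3.17 (glycolysis) to 4.47 (ribosomal proteins), and under TMM those of glycolysis (-0.32) and the integrated stress response (-0.18) turned negative, as did GARS1, WARS1, SDHA, NDUFS1 and SQLE. Against other genes, camera called 0 of these 9 lists (lowest adjusted p 0.497, and 0 with an estimated correlation). In contrast fry, which tests a list on its own, called 9. camera placed glycolysis, the integrated stress response and the cell cycle below other genes although their medians and means were positive. Without APOBEC1-only replicate 1, 2 or 3, camera called 2 lists each time, the unfolded protein response chaperones and heat shock genes.

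Editing per covering read asked the same question per read, on isoforms edited in every library. Such an isoform held at least 1 edited read in each APOBEC1-only library, so its lowest possible value there depended on its coverage. Expression was therefore not fully divided out. How far this shaped the size and ranking of the rises, for genes or lists, was not tested. RPS2 rose most under the naming rule, from 1.47 ± 0.487 to 152 ± 22.5 edited reads per 100 covering reads (logit change 6.34 ± 0.30 SE, adjusted p = 1.51e-11), followed by EEF1A1, from 1.15 ± 0.217 to 87.4 ± 12.7. TRAP1, the mitochondrial HSP90, rose from 0.956 ± 0.280 to 63.8 ± 1.17, and the ATP synthase subunits ATP5F1A and ATP5F1B reached 67.9 ± 16.8 and 71.7 ± 1.75 from 1.54 ± 0.883 and 1.53 ± 0.827. EIF3L, HSP90AA1, UBA1 and HSPD1 were also among the largest rises, with logit changes of 5.42 to 5.56. The spliceosome proteins PRPF8 (from 11.8 ± 2.78 to 212 ± 64.8) and SNRNP200 (from 7.55 ± 5.03 to 169 ± 29.1), named after their values were seen, also passed 100, which is possible because edited reads are summed over positions. The smallest rises among named genes were those of AARS1, an aminoacyl-tRNA synthetase (from 4.54 ± 0.943 to 21.7 ± 1.28), and MAP1B, a microtubule-associated protein (from 5.43 ± 1.00 to 27.0 ± 3.49). These 2 rose less than the median gene, and after centring on it their log2 changes were -1.30 each.

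Of 392 genes tested with limma for editing per read, 375 rose and 0 fell (0 falls also with coverage weights), with a median logit change of 3.47. No gene fell in the main test at an unadjusted p under 0.05, as the 375 rises were all the genes past it, and without Ribo-STAMP replicate 3 there was 1 fall, TRMT61B (logit change -1.24), named after its values were seen. Centring each library on its median gene moved the median to 0.10, and 72 genes were then higher and 52 lower. The rise was smaller for longer transcripts, by 0.35 per doubling of length across genes (95% interval of the slope -0.54 to -0.17), with medians of 3.74, 3.57, 3.29 and 3.08 from the shortest to the longest of 4 length groups. Genes are not independent replicates, and the read-weighted transcript length did not separate the groups (3259 ± 107 against 3536 ± 465 bases, exact permutation p = 0.5).

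All tested members of 7 lists rose per covering read, with the same counts adjusted over the list alone. They were 12 translation factors (median logit change 4.30), 13 heat shock genes (4.19), 6 unfolded protein response chaperones (4.56), 11 cell cycle genes (3.88), 9 glycolysis genes (4.13), 6 cytoskeleton genes (4.24) and 6 integrated stress response genes (2.41, and -0.96 after centring on the median gene). PKM, which makes pyruvate, rose from 1.29 ± 0.247 to 40.4 ± 7.78 edited reads per 100, the cytoplasmic actin ACTB from 1.39 ± 0.0915 to 54.6 ± 12.1 and HSP90AB1 from 2.14 ± 0.0742 to 68.7 ± 6.40. Lists with fewer than 5 tested members included oxidative phosphorylation, where NDUFS1 rose from 3.38 ± 1.73 to 40.5 ± 11.2, and the proteasome, where PSMD2 rose from 1.92 ± 0.887 to 79.6 ± 14.1. camera placed 2 lists above other genes, translation factors and heat shock, at an adjusted p of 0.0219 each. With an estimated correlation the adjusted p was 0.295 for both, and fry called 7 lists. camera put the integrated stress response below other genes despite its positive median and mean (adjusted p = 0.217). Without APOBEC1-only replicate 3 only heat shock was called (adjusted p = 0.0154). The unfolded protein response was called as well without APOBEC1-only replicate 1 (0.0268) and after centring on the median gene (0.0253).

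**Figure D2:**
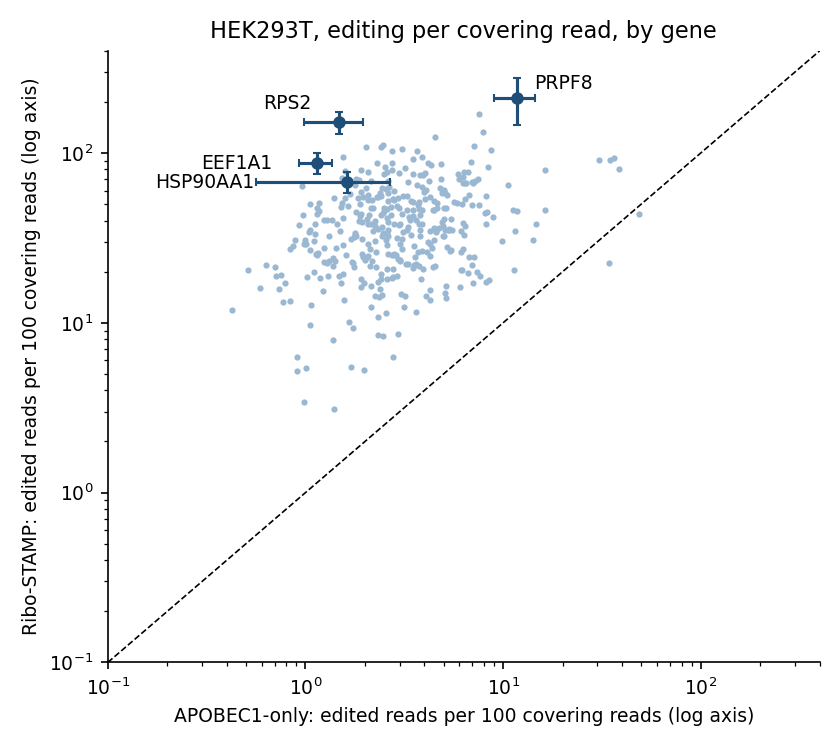
Each point is 1 of the 392 genes tested for editing per covering read in HEK293T, with the mean of the 3 APOBEC1-only libraries on the x axis and of the 3 Ribo-STAMP libraries on the y axis (edited reads per 100 covering reads, both axes logarithmic); error bars on the named genes are SD and the dashed line marks equality. RPS2 reached 152 and PRPF8 212 edited reads per 100 with Ribo-STAMP, and after centring on the median gene 72 genes were higher and 52 lower.

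The MDA-MB-231 libraries applied the method to a model of hypoxia, and the first question was whether CoCl2 changed editing as a whole. Depth-matched edited reads were 159120 ± 11280 in untreated and 172929 ± 6208 in CoCl2 libraries (SD, n = 2 each, ratio 1.09, exact permutation p = 0.333, the smallest that 2 against 2 allows). Edited reads per 1000 reads on listed isoforms were 148 ± 11.3 and, lower in CoCl2, 141 ± 3.12 (ratio 0.955, exact permutation p = 0.667). Editing of the median gene was 17.9 ± 0.00960 and 20.3 ± 0.488 edited reads per 100 covering reads (exact permutation p = 0.333). In this line 80.9 ± 0.491% of positions in untreated cells had A or U before the edited C, against 43.3% of all coding C of the listed isoforms. The CoCl2 value differed by -0.90 percentage points (exact permutation p = 0.333). Edited positions lay at a median of 0.509 ± 0.00120 and 0.508 ± 0.00177 of the way along the coding sequence (exact permutation p = 0.667). The median distance to the stop codon was 678 ± 45.3 and 570.5 ± 2.12 bases (exact permutation p = 0.333). Read-weighted transcript length was 2366 and 2207 bases in the untreated and 1924 and 1962 bases in the CoCl2 libraries (exact permutation p = 0.333).

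Coverage of edited isoforms, a stand-in for mRNA abundance, was compared between CoCl2 and untreated cells. The values of this paragraph are as measured and include a trend with transcript length. With that trend taken out, 38 genes named by the rule stayed on their side of the threshold, 46 lost their call and 6 changed sign. WDR83 (GRCh38 chromosome 19, 12666800 to 12675832, plus strand), which encodes a WD-repeat protein, had the largest rise under the naming rule, from 20.8 ± 2.77 to 62.8 ± 0.416 scaled covering reads (log2 change 1.55, adjusted p = 0.00213). BNIP3, a hypoxia-induced mitophagy receptor (chromosome 10, 131966455 to 131982013, minus strand), rose from 211 ± 6.96 to 624 ± 108 (log2 change 1.55 ± 0.21 SE, adjusted p = 0.000627). GAPDH, of glycolysis (chromosome 12, 6533927 to 6538374, plus strand), rose from 7181 ± 1379 to 19633 ± 1687, the cytokine MIF from 136 ± 23.5 to 375 ± 8.38, and VKORC1, which recycles vitamin K, from 37.4 ± 5.86 to 105 ± 1.43. FCGRT, COMMD4, NARF, C1orf35 and PRADC1 were the other members of the 10 largest rises under the rule. TM9SF3, a transmembrane protein (chromosome 10, 96518109 to 96587452, minus strand), fell most under that rule, from 63.5 ± 28.4 to 9.41 ± 4.08 (log2 change -2.62, adjusted p = 0.00118). The isocitrate dehydrogenase IDH1 fell from 72.0 ± 29.8 to 17.4 ± 1.48 and the histone demethylase KDM1A from 204 ± 113 to 51.7 ± 2.29 (n = 2 each). SLC20A1, a phosphate transporter, fell from 133 ± 34.1 to 38.6 ± 2.38, and TNPO1, CAB39, USO1, UTP25 and PLCD3 were also among the largest falls. Among named list members, the non-muscle myosin MYH9 fell from 184 ± 3.49 to 61.6 ± 17.5, PABPC1 from 587 ± 167 to 205 ± 30.1 and the release factor GSPT1 from 330 ± 157 to 107 ± 1.47.

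Of 5675 genes tested with limma, 1369 rose and 1092 fell, and both numbers moved with transcript length. In the shortest of 4 length groups (median 1265 bases) 906 genes rose and 14 fell, and in the longest (4887 bases) 74 rose and 452 fell. The log2 change fell by 0.52 per doubling of length (95% interval of the slope -0.54 to -0.51, Spearman -0.64, across genes, which are not independent replicates). Untreated replicate 2 differed from untreated replicate 1 the same way, with a slope of -0.29, and CoCl2 replicate 2 from replicate 1 with a slope of 0.01. With the length trend taken out, 484 genes rose and 366 fell, and 574 genes were called in the same direction both ways. The counts also moved when single libraries were left out, since the spread then comes from the other group's 2 libraries alone. Changes moved less without a CoCl2 library: the ribosomal list median was 0.75 and 0.72 without CoCl2 replicates 1 and 2, against 0.76 with all libraries. Without untreated replicates 1 and 2 it was 0.61 and 0.93. Without CoCl2 replicate 1, 0 genes rose and 13 fell with limma (1392 at an unadjusted p under 0.05). Without CoCl2 replicate 2, GAPDH and BNIP3 rose and 21 genes fell. Calls numbered 2300 and 3793 without untreated replicates 1 and 2. In each of these fits the lone library of a group is assumed to vary like the others. Isoforms listed in any library gave 790 rises and 295 falls.

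**Figure D3:**
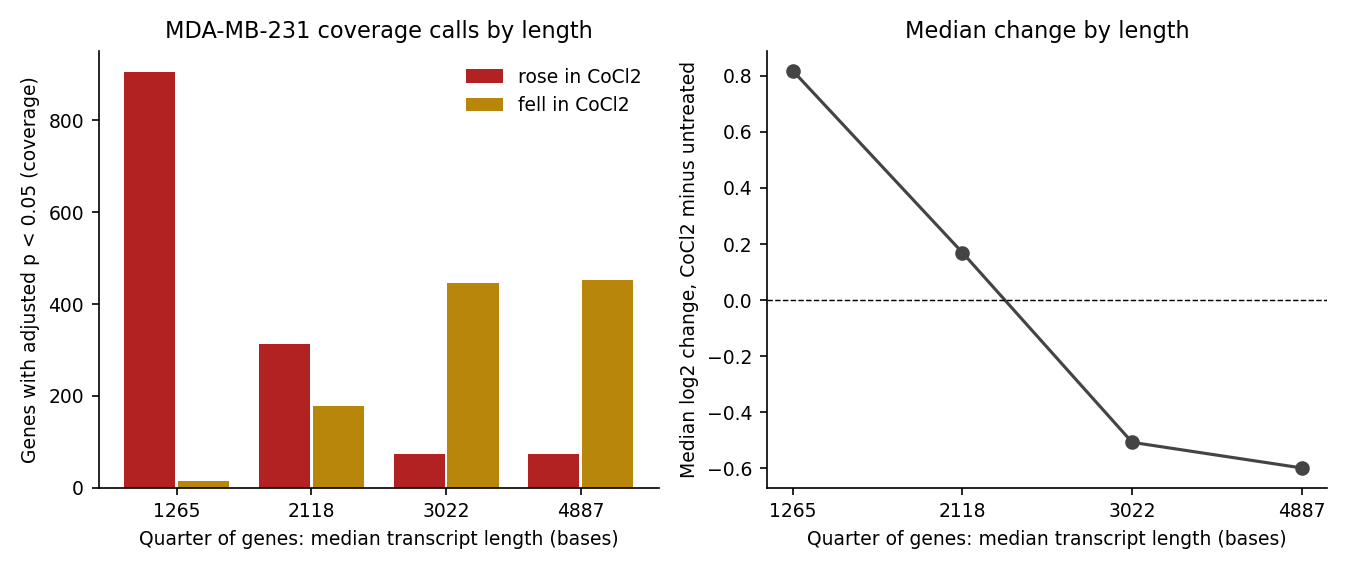
Genes whose coverage rose or fell in CoCl2-treated MDA-MB-231 cells at an adjusted p under 0.05 (left, bars) and the median log2 change, CoCl2 minus untreated (right, points joined by a line), by transcript length in 4 equal groups, each labelled with its median in bases (n = 2 libraries per group). The medians ran from 0.82 in the shortest to -0.60 in the longest group.

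Among hypoxia-induced genes, 6 of 27 rose and 1, SLC2A1, fell (6 and 1 adjusted over the list alone). Besides BNIP3, rises were those of ADM, which encodes the peptide adrenomedullin, from 57.3 ± 11.1 to 148 ± 0.448, the mTORC1 inhibitor DDIT4 from 384 ± 1.66 to 828 ± 70.8 and JMJD6 from 79.5 ± 18.4 to 178 ± 9.66. The list's members were long (median 3052 bases), its median log2 change was 0.08, and camera called it only with the length trend taken out (median 0.36, adjusted p = 0.000387, against 0.373 as measured). Its adjusted p without the trend was 0.331 with an estimated correlation. Of 15 glycolysis genes 9 rose and 2, SLC2A1 and HK1, fell (9 and 2 adjusted over the list alone; median 0.59, or 0.49 without the trend). ALDOA rose from 1157 ± 190 to 2774 ± 164, PGK1 from 2355 ± 462 to 4803 ± 26.2 and the lactate exporter SLC16A3 from 2291 ± 68.4 to 4886 ± 18.1. The metal and oxidative response rose in 12 of 20 genes and fell in 2, SLC30A1 and SRXN1 (12 and 2 adjusted over the list alone; median 0.69, or 0.27 without the trend). It included the ferritin chains FTL, from 4153 ± 993 to 9957 ± 34.3, and FTH1, from 2621 ± 739 to 5540 ± 723. Heat shock genes fell in 11 of 20 cases and rose in 2, HSPB1 and HSPE1 (2 rises and 11 falls adjusted over the list alone; median -0.57, or -0.22 without the trend). HSP90AB1 fell from 3244 ± 1209 to 1420 ± 130 and HSP90AA1 from 1931 ± 732 to 865 ± 36.6. For hypoxia, glycolysis, the metal response and heat shock in that order, rises and falls were 7 and 0, 9 and 0, 5 and 0, and 0 and 7 without the length trend. Leaving out untreated replicate 1 gave 8 and 2, 9 and 1, 13 and 0, and 2 and 13, and leaving out untreated replicate 2 gave 10 and 7, 10 and 3, 13 and 4, and 5 and 12. Without CoCl2 replicate 1 limma called 0 members of these lists (1392 of all genes at an unadjusted p under 0.05), and without CoCl2 replicate 2 only BNIP3 and GAPDH.

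Several lists held short transcripts. Of 75 cytosolic ribosomal proteins, with a median length of 933 bases, 61 rose and 0 fell (67 and 0 adjusted over the list alone). Among them were RPL5, from 1777 ± 245 to 3868 ± 284, and RPS2 itself, from 1485 ± 182 to 2581 ± 188. Their median of 0.76 became -0.02 without the length trend, and RPS2 turned from 0.80 to -0.06. Nuclear-encoded oxidative phosphorylation (991 bases) rose in 45 of 59 genes and fell in 1, NDUFS1 (47 and 1 adjusted over the list alone; median 0.85, or 0.12 without the trend). CYC1, a subunit of complex III, rose from 627 ± 90.3 to 1255 ± 101. The proteasome (1580 bases) rose in 22 of 29 genes and fell in 2, PSMD1 and PSMD2 (23 and 2 adjusted over the list alone; median 0.81, or 0.25 without the trend). PSMB5, a catalytic subunit, rose from 213 ± 33.2 to 470 ± 14.4. Mitochondrially encoded genes (1042 bases) rose in 4 of 9 cases and fell in 0 (4 and 0 adjusted over the list alone). Without the trend their median turned from 0.16 to -0.71, and MT-CO1, MT-CO2, MT-CO3 and MT-CYB, the 4 that rose, turned negative. Interferon response genes (1233 bases) rose in 6 of 13 cases and fell in 1, IFIT3 (6 and 2 adjusted over the list alone). B2M rose from 900 ± 155 to 1629 ± 9.50 (log2 change 0.87, and -0.00295 without the trend, as was the list median, 0.65 as measured). For these 5 lists in order, rises and falls with limma were 13 and 0, 13 and 0, 7 and 0, 0 and 5, and 0 and 2 once the length trend was taken out (1748 of all genes at an unadjusted p under 0.05). The falls were MT-ND1, MT-ND2, MT-ND4, MT-ND5 and MT-ATP6, and IFIT1 and IFIT3, named after their values were seen. Leaving out untreated replicate 1 gave 59 and 0, 43 and 2, 21 and 3, 4 and 2, and 4 and 2, and leaving out untreated replicate 2 gave 72 and 0, 52 and 1, 25 and 3, 6 and 1, and 6 and 3. Without CoCl2 replicate 1 or 2 limma called 0 members of these lists (1392 and 1482 of all genes at an unadjusted p under 0.05).

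The remaining lists had rises and falls side by side. Counts were 12 and 11 of 37 translation factors (13 and 13 adjusted over the list alone), 4 and 5 of 18 integrated stress response genes and 3 and 6 of 19 unfolded protein response chaperones. Counts were 6 and 5 of 20 tricarboxylic acid cycle genes (6 and 6 adjusted over the list alone), and 9 and 8 of 35 cell cycle genes (9 and 9). They were 3 and 4 of 17 cholesterol and fatty acid synthesis genes, 7 and 6 of 30 extracellular matrix genes, 13 and 8 of 28 cytoskeleton genes (14 and 9), and 4 and 2 of 10 MDA-MB-231 markers. Lists with no second pair of counts kept theirs adjusted over the list alone. For these 9 lists in order, rises and falls with limma were 6 and 4, 3 and 2, 0 and 2 (HSP90B1 and CALR), 3 and 1, 5 and 3, 1 and 0, 3 and 2, 3 and 2, and 1 and 1 without the length trend (1748 of all genes at an unadjusted p under 0.05). Leaving out untreated replicate 1 gave 12 and 14, 4 and 3, 3 and 9, 7 and 4, 11 and 11, 3 and 0, 8 and 5, 15 and 9, and 4 and 2. Leaving out untreated replicate 2 gave 15 and 14, 7 and 9, 3 and 9, 8 and 9, 14 and 12, 4 and 9, 8 and 16, 16 and 12, and 4 and 4. Without CoCl2 replicate 1 or 2, 0 members of these lists rose with limma (1392 and 1482 of all genes at an unadjusted p under 0.05), and the falls were PABPC1 without replicate 1 and MYH9 and TLN1 without replicate 2. In this line the HEK293T markers STMN1 and CKB rose and MAP1B fell. camera called 6 lists, namely glycolysis and heat shock (adjusted p = 0.0131 each), the metal and oxidative response (0.00297), the proteasome (3.1e-06), oxidative phosphorylation (7.43e-11) and ribosomal proteins (1.61e-15). With an estimated correlation the adjusted p was 0.581 for all 6, and fry called 0 lists at an adjusted p and the lowest it gave was 0.0615. Without the length trend 7 lists were called, with hypoxia above and mitochondrially encoded genes below the rest and ribosomal proteins no longer called (adjusted p = 0.601), but with an estimated correlation the adjusted p was 0.331 to 0.724 for these 7. Leaving out CoCl2 replicate 1 ended the call for heat shock, untreated replicate 1 added the unfolded protein response and the cytoskeleton, and untreated replicate 2 added mitochondrially encoded genes. For translation factors camera's direction was up and the median negative, and for the cell cycle the median was positive and the mean negative.

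**Figure D4:**
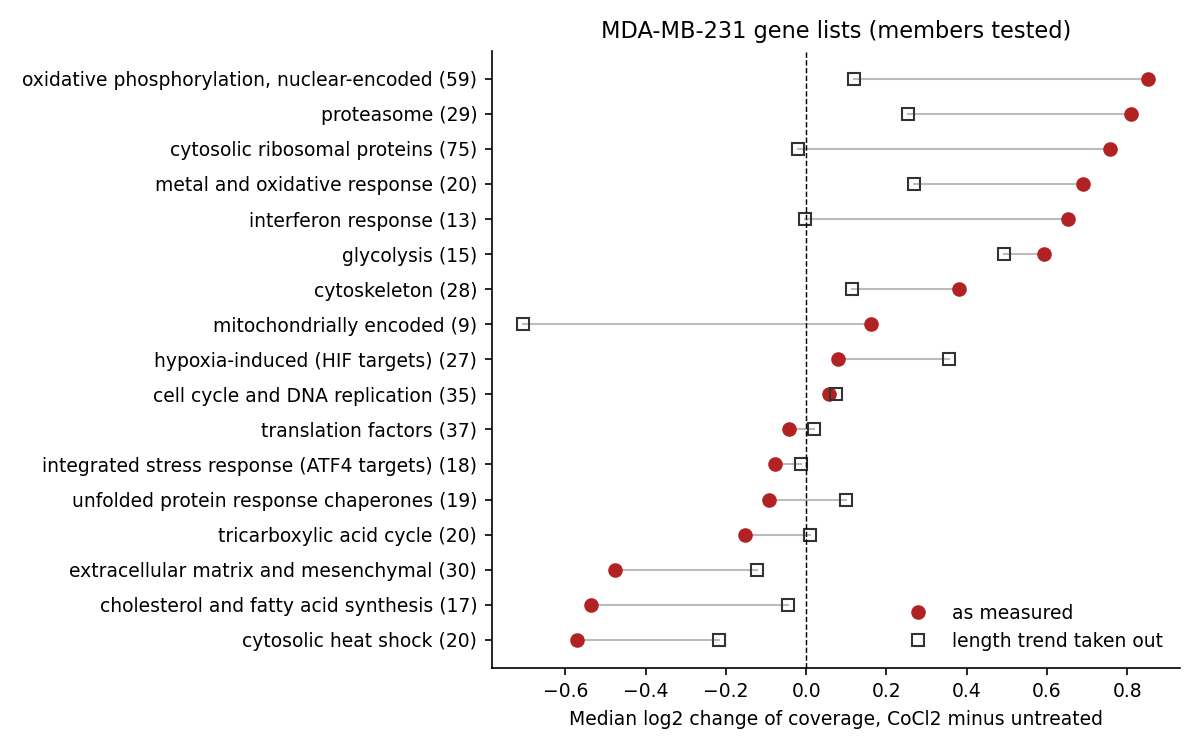
Median log2 change of coverage, CoCl2 minus untreated (x axis), of 17 gene lists in MDA-MB-231 cells with the number of members tested (y axis); filled circles are values as measured, open squares those with the length trend taken out of each library, and grey lines join them (n = 2 libraries per group). Ribosomal proteins moved from 0.76 to -0.02 and mitochondrially encoded genes from 0.16 to -0.71, while hypoxia-induced genes moved from 0.08 to 0.36 and glycolysis from 0.59 to 0.49; the interferon response, translation factors, unfolded protein response and tricarboxylic acid cycle also changed sign.

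Edited reads per gene, which join mRNA abundance and editing per read, followed a similar course. BNIP3 rose from 20.4 ± 10.2 to 121 ± 16.3 depth-scaled edited reads (log2 change 2.59 ± 0.39 SE, adjusted p = 0.0298). FCGRT, the neonatal Fc receptor, rose from 9.96 ± 3.42 to 55.6 ± 12.8 and the deacetylase SIRT2 from 11.8 ± 0.594 to 64.9 ± 4.68. NARF rose from 12.3 ± 2.76 to 62.1 ± 3.63, and MRPL15, EMP3, EMC4, MIF, ARL6IP4 and MYL12B completed the 10 largest rises. NCBP1, of the nuclear cap-binding complex, fell from 55.9 ± 15.7 to 11.5 ± 5.53, the import receptor TNPO1 from 53.9 ± 33.2 to 11.2 ± 7.13 and PABPC1 from 147 ± 45.3 to 41.8 ± 22.3 (n = 2 each). TYK2, MOV10, ATF6, NCAPG2, TBCD, ARHGAP1 and CAPZA1 were the others of the 10 largest falls. RPS2 rose from 57.4 ± 11.8 to 132 ± 19.6 (log2 change 1.19, and -0.00176 without the length trend).

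Of 4097 genes tested with limma, 495 rose and 119 fell, with a median log2 change of 0.19 over all genes. Under TMM, which moved that median to -0.01, 212 rose and 200 fell, and with no scaling (median 0.04) 0 genes were called with limma (1418 at an unadjusted p under 0.05). Rises again concentrated in the shortest of 4 length groups (327 rises, 0 falls) and falls in the longest 2 (58 and 51), with a slope of -0.63 per doubling, and 107 genes rose and 64 fell once the length trend was taken out. Without CoCl2 replicate 1, BNIP3 and SIRT2 rose and 9 genes fell, without CoCl2 replicate 2, BNIP3, FCGRT and GAPDH rose and 6 fell, and without untreated replicate 2 there were 1657 calls. Among genes in the edited-read and coverage tests (4042), 473 of 494 that rose in edited reads also rose in coverage and 0 fell, and 109 of 116 that fell also fell in coverage and 0 rose. Across genes the log2 changes of edited reads and coverage had a Spearman correlation of 0.91, with genes not independent replicates and both measures drawn from the same reads.

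In this measure 2 of 19 hypoxia-induced genes rose, BNIP3 and BNIP3L, the latter from 20.4 ± 3.48 to 55.3 ± 3.14, and 7 of 15 glycolysis genes, including PGK1 from 50.7 ± 3.68 to 168 ± 1.11. Rises numbered 34 of 74 ribosomal proteins, 20 of 58 oxidative phosphorylation genes, 12 of 29 proteasome genes, 8 of 15 metal and oxidative response genes and 8 of 26 cytoskeleton genes. They were 7 of 38 translation factors (PABPC1 and GSPT1 fell), 5 of 20 tricarboxylic acid cycle genes, 3 of 33 cell cycle genes (TK1, TUBA1B and UBE2C, while RRM1 and TOP2A fell) and 3 of 30 extracellular matrix genes (ANXA2, TIMP1 and PLAUR). The remaining rises were 2 of 14 cholesterol synthesis genes (FDPS and EBP), 2 of 9 interferon response genes (ISG15 and B2M) and 1 of 10 line markers (KRT18). The list of 17 unfolded protein response chaperones had 1 rise, CRELD2, and 1 fall, HSP90B1, the 15 integrated stress response genes 1 rise, PYCR1, and the 8 mitochondrially encoded genes 0. In the heat shock list 3 of 20 genes fell, HSP90AA1 (from 206 ± 99.2 to 75.4 ± 25.5), HSPA9 and HSPD1. Adjusted over the list alone, rises and falls were 44 and 0 for ribosomal proteins, 30 and 0 for oxidative phosphorylation, 19 and 1 for the proteasome, 12 and 3 for the cytoskeleton and 12 and 6 for translation factors. Counts on this basis were 9 and 1 for the metal response, 7 and 1 for glycolysis, 5 and 3 for the cell cycle, 5 and 1 for the tricarboxylic acid cycle, 4 and 2 for line markers and 0 and 1 for the unfolded protein response. For ribosomal proteins, oxidative phosphorylation and the proteasome, taking the length trend out left 5, 5 and 4 rises, with medians of 0.16, 0.34 and 0.31 against 1.2, 1.24 and 1.05 as measured. TMM left 15, 11 and 7, and without untreated replicate 2 there were 56, 38 and 23. For glycolysis, the metal response and the cytoskeleton these counts were 3, 3 and 1 without the trend, 6, 3 and 3 under TMM, and 8, 8 and 13 without untreated replicate 2 (with 3, 1 and 7 falls), and leaving out untreated replicate 1 gave 12 rises in the cytoskeleton list. The other lists were, in order, hypoxia, translation factors, tricarboxylic acid cycle, cell cycle, extracellular matrix, cholesterol synthesis, interferon response, line markers, unfolded protein response, integrated stress response, mitochondrially encoded and heat shock. Their rises and falls with limma were 2 and 0, 4 and 2, 1 and 1, 0 and 0, 0 and 1, 0 and 0, 0 and 0, 0 and 1, 0 and 1, 0 and 0, 0 and 1, and 0 and 2 without the length trend (901 of all genes at an unadjusted p under 0.05). Under TMM (1556 at that level) they were 2 and 0, 1 and 5, 2 and 1, 3 and 3, 3 and 2, 1 and 0, 1 and 0, 0 and 2, 0 and 1, 0 and 1, 0 and 0, and 0 and 6. Without untreated replicate 1 they were 2 and 0, 8 and 4, 4 and 1, 4 and 2, 4 and 1, 3 and 0, 3 and 0, 2 and 1, 0 and 1, 1 and 1, 0 and 0, and 0 and 3. Without untreated replicate 2 they were 5 and 2, 14 and 10, 9 and 5, 12 and 9, 7 and 7, 2 and 3, 4 and 0, 4 and 4, 1 and 3, 4 and 4, 4 and 0, and 3 and 9. Without CoCl2 replicate 1 BNIP3 alone rose among list members, and without CoCl2 replicate 2 BNIP3 and GAPDH, so limma called 0 rises in the 3 lists first named (846 and 913 of all genes at an unadjusted p under 0.05). NQO1, a quinone reductase, rose from 34.1 ± 13.2 to 114 ± 6.16 and SDHB, of complex II, from 19.5 ± 7.5 to 71.8 ± 7.18.

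camera called 5 lists in edited reads: heat shock below other genes (adjusted p = 0.0176) and the metal and oxidative response (0.00424), proteasome (8.87e-06), oxidative phosphorylation (3.22e-08) and ribosomal proteins (4.39e-11) above. With an estimated correlation the adjusted p was 0.550 to 0.575 for these 5, and fry called 6 lists. The median transcript of the ribosomal list was 932 bases long and that of the oxidative phosphorylation list 1036. Taking the length trend out ended the ribosomal call (adjusted p = 0.102) and added hypoxia (0.00728), glycolysis (0.00348) and, below other genes, mitochondrially encoded genes (0.00568), whose median turned from 0.40 to -0.72. These 3 had adjusted p values of 0.3, 0.3 and 0.563 with an estimated correlation. The medians of the interferon response (-0.18), cytoskeleton (-0.03) and line markers (-0.17) also turned negative without the trend. Leaving out CoCl2 replicate 1 ended the heat shock call, as did CoCl2 replicate 2, and glycolysis was called without untreated replicate 1 or 2 or CoCl2 replicate 2. Medians of cholesterol synthesis (-0.08) and the extracellular matrix (-0.16) were negative while their means were positive. For the cell cycle and the line markers camera's direction was down while their medians were positive. Under TMM the median of the tricarboxylic acid cycle turned from 0.08 to -0.11.

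Editing per covering read asked whether editing changed beyond mRNA abundance in CoCl2. MDA-MB-231 had no APOBEC1-only libraries, so a change in translation cannot be told apart from one in the editor's background or level. No single gene passed the threshold. Among the highest-ranked was PSMA4, a proteasome subunit, at 13.9 ± 0.480 untreated and 32.0 ± 10.2 edited reads per 100 in CoCl2. Next came the mitochondrial RNA-binding protein SLIRP at 5.75 ± 0.485 and 17.5 ± 1.64, and thymidine kinase TK1 at 4.43 ± 0.130 and 9.16 ± 1.43 (n = 2 each, adjusted p = 0.264 for all 3, of which SLIRP was chosen after its values were seen). BNIP3 stood at 9.74 ± 5.05 and 19.5 ± 0.843 (adjusted p = 0.292) and RPS2 at 3.81 ± 0.237 and 5.10 ± 0.367 (adjusted p = 0.497). Of the hypoxia list, SLC2A1, the glucose transporter, stood at 5.80 ± 0.869 and 4.98 ± 0.260 (adjusted p = 0.713). GAPDH, at 0.906 ± 0.437 and 1.30 ± 0.0537, and PGK1, at 2.18 ± 0.295 and 3.51 ± 0.0203, lay far below the median gene at the listed positions. Positions held by all 4 MDA-MB-231 libraries are absent, and how far this lowers the levels of deeply covered genes was not tested. At the other end stood COL6A1, a collagen chain, at 78.1 ± 10.5 and 121 ± 3.51 (adjusted p = 0.313).

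Of 5643 genes, limma called 0 (553 at an unadjusted p under 0.05, lowest adjusted p 0.264), and limma with coverage weights also 0 (563). Without a filter on coverage 1 of 6021 genes rose, PI4KA (adjusted p = 0.0358, against 0.0938 to 0.656 as the lowest value over the other filters, weights, added values, centring and left-out libraries), named after its values were seen. The median logit change over all genes was 0.20, and 0.01 after centring on the median gene. Across genes the change in editing per read had a Spearman correlation of 0.06 with the change in coverage, genes not being independent replicates.

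As groups, camera placed 5 lists above other genes: ribosomal proteins (median logit change 0.42, adjusted p = 0.000421), oxidative phosphorylation (0.40, 0.00337), the proteasome (0.34, 0.00617), the cytoskeleton (0.34, 0.0366) and the metal and oxidative response (0.42, 0.037). The integrated stress response lay below (-0.05, adjusted p = 0.037). With an estimated correlation the adjusted p was 0.486 to 0.514 for these 6, with the length trend taken out camera called 0 lists (lowest adjusted p 0.0654), and fry called 1, the proteasome (0.01). In the order named, the 6 medians without the trend were 0.13, 0.14, 0.09, 0.12, 0.17 and -0.23, with a median of 0.01 over all genes. They were 0.23, 0.21, 0.14, 0.14, 0.23 and -0.24 after centring on the median gene instead. After centring on the median gene camera called ribosomal proteins (0.00455), oxidative phosphorylation (0.0085) and the integrated stress response (0.0182). No member of any list passed the threshold over all genes. Adjusted over the list alone, 4 cytoskeleton genes (TUBB4B, TUBB, MYH9 and MYL12B), 3 proteasome genes (PSMA4, PSMA6 and PSMB1) and 3 glycolysis genes (PGAM1, PGK1 and ALDOA) rose. So did 1 gene each of the hypoxia (BNIP3), metal (NQO1), tricarboxylic acid cycle (SDHB) and cell cycle (TK1) lists, and 0 genes of the other 11 lists. Leaving out untreated replicate 1 left 4 lists called, the proteasome, the metal response, the cytoskeleton and the integrated stress response. Without untreated replicate 2, or without CoCl2 replicate 2, ribosomal proteins and oxidative phosphorylation alone were called, to which the proteasome was added without CoCl2 replicate 1. Lists not called by camera had medians of 0.02 (interferon response) to 0.34 (tricarboxylic acid cycle). Of these, 6 (hypoxia, unfolded protein response, heat shock, mitochondrially encoded, cholesterol synthesis and interferon response) lay below other genes by camera although their medians and means were positive. After centring, the medians of hypoxia-induced genes (-0.07), glycolysis (-0.00014), heat shock (-0.06), the unfolded protein response (-0.16), mitochondrially encoded genes (-0.09), the cell cycle (-0.10), the interferon response (-0.17) and the line markers (-0.04) turned negative.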

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

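Chosen only after the data were seen were the other values added before the log, the sets without both HEK293T libraries numbered 3, and the removal of the length trend. Of the values that answer a comparison, 95 kept direction and side of the threshold (or stayed within 1.5 times), 27 moved, 9 were weaker, 6 stronger and 1 reversed. That 1 is the place of edited positions in MDA-MB-231, where the difference in distance to the stop codon was -107.5 bases. HEK293T position sharing was 38.3% at positions covered by at least 20 reads. Of the named-gene alternatives in HEK293T, 979 were kept, 54 weaker and 5 reversed for edited reads, and 647, 13 and 10 for editing per read. All of the 54 and 5 came from TMM, under which 0 named genes were kept. All of the 13 and 10 came from centring on the median gene, under which 25 were kept. In MDA-MB-231, 754 were kept, 230 weaker and 6 reversed for coverage. Taking the length trend out gave 46 of these weaker and all 6 reversed. For edited reads 934 were kept, 446 weaker, 50 stronger and 1 reversed. Editing per read had 878 kept and 6 stronger. No gene was called there in the main test, so none could become weaker. Kept then means that a gene stayed uncalled, and a change of sign in an uncalled gene was not counted. Except where the number of genes tested or of libraries required changed, the cause was not tested.

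Counts of called genes moved with scaling, filter, length and left-out libraries. HEK293T edited reads gave 26 under TMM, 2267 with no filter (7004 genes tested) and 212 with at least 30 edited reads (212 tested), and editing per read gave 124 after centring on the median gene. MDA-MB-231 edited reads gave 0 with no scaling, 0 with no filter (9753 tested) and 0 from the number of positions with limma (1418, 1771 and 1369 at an unadjusted p under 0.05), 205 at positions covered by at least 20 reads and 171 without the length trend. MDA-MB-231 coverage gave 1085 from isoforms listed in any library and 850 without the length trend, and editing per read 1 with no filter (PI4KA). Leaving out each library gave 757 to 1066 calls for HEK293T edited reads, 364 to 375 for HEK293T editing per read, 9 to 1657, 13 to 3793 and 0 to 0 for MDA-MB-231 edited reads, coverage and editing per read, and ratios of edited reads per library of 16.2 to 17.3 in HEK293T and 1.03 to 1.14 in MDA-MB-231. In MDA-MB-231 the lone library left in a group is assumed to vary like the others.

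Gene lists called by camera depended on the correlation. With an estimated correlation 0 lists were called in HEK293T editing per read and 0, 0 and 0 in MDA-MB-231 edited reads, coverage and editing per read. fry called 9 lists in HEK293T edited reads, 7 in HEK293T editing per read, 0 in MDA-MB-231 coverage and 1 in MDA-MB-231 editing per read. MDA-MB-231 editing per read had 3 lists after centring and 0 without the length trend, and HEK293T editing per read 1 without both libraries numbered 3. Leaving out each library gave 0 to 2 and 1 to 3 lists in HEK293T (edited reads, editing per read) and 4 to 6, 5 to 8 and 2 to 4 in MDA-MB-231 (edited reads, coverage, editing per read).

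Under TMM the log2 changes in HEK293T edited reads were -0.18 for GARS1, -0.23 for WARS1, -0.10 for SDHA, -0.39 for NDUFS1 and -0.20 for SQLE. After centring, HEK293T editing per read was -0.0868 for EIF4G2, -1.30 for AARS1, -0.83 for WARS1, -0.73 for DLAT, -0.63 for FDFT1, -0.45 for ITGB1, -0.39 for LAMC1, -0.20 for PSMD3 and -1.30 for MAP1B. Without the length trend MDA-MB-231 coverage was -0.0617 for RPS2, -0.0779 for MT-CO3, -0.11 for MT-CO2, -0.24 for MT-CYB, -0.11 for MT-CO1 and -0.00295 for B2M, and edited reads -0.00176 for RPS2. These scalings subtract a common or length-dependent change by construction.

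With the replicate number as a block, calls were 654 and 382 in HEK293T edited reads and editing per read, and 1088, 2434 and 15 in MDA-MB-231 edited reads, coverage and editing per read (the 1 fall among the 15 was PPP2R3C, named after its values were seen). Under the block camera also called the unfolded protein response in HEK293T editing per read (adjusted p = 0.0427) and glycolysis in MDA-MB-231 edited reads (0.0362), and no longer the integrated stress response and metal response in MDA-MB-231 editing per read (0.0553 each). It changed no other list call. Deviations of libraries sharing a number correlated across genes at 0.09, 0.12 and 0.33 in HEK293T edited reads and 0.13, 0.04 and 0.22 in editing per read, and at 0.23, 0.44 and 0.58 in HEK293T coverage, which was not tested between groups. Not every HEK293T sample correlated best with its own number: APOBEC1-only replicate 2 did so with Ribo-STAMP replicate 1 in edited reads (0.15), editing per read (0.07) and coverage (0.44), and APOBEC1-only replicate 1 with Ribo-STAMP replicate 2 in edited reads (0.18) and coverage (0.58). A stricter confidence score was not run, since the files hold no scores. The DESeq2 alternative was not run, since the design kept count models for files with counts in a column of their own, although the summed edited reads are whole numbers. limma-voom was run on those sums and called 648 genes in HEK293T and 704 in MDA-MB-231. The HEK293T edited-read test recovered 6.45% of simulated 2-fold changes at a dispersion of 0.184, with both groups simulated at the Ribo-STAMP level, and the effect of depth was not tested.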

Other observations

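Isoform pairs were compared only after the other results were seen. In MDA-MB-231, 419 genes had 2 isoforms covered and edited enough to compare over the coding positions both contain, in all 4 libraries, and 15 differed in editing per read (limma). PLAUR, the urokinase receptor, carried 6.33 ± 2.13 edited reads per 100 on its 1548-base isoform and 27.7 ± 2.20 on its 1254-base isoform (SD, n = 4 libraries, log2 difference -2.25, adjusted p = 0.00135). LRR1 carried 3.02 ± 1.30 and 23.5 ± 6.82 on isoforms of 1745 and 957 bases, and the kinase GRK6 7.39 ± 0.236 and 20.2 ± 5.70 on isoforms of 2939 and 1660 bases. In the other direction PIGS, which helps attach GPI anchors, carried 49.7 ± 6.28 on its more covered isoform (2877 bases) and 17.1 ± 4.97 on the other (2815 bases). The other 11 genes were AMZ2, ADRM1, RHBDD2, RAB34, HDLBP, C7orf50, SLC29A1, RPS10, NDUFV3, TSC22D4 and AJUBA.

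Among these 15 genes the more covered isoform was edited more in 4 and less in 11, and the longer isoform likewise more in 4 and less in 11, with a median absolute log2 difference of 1.45. The difference between isoforms changed with CoCl2 in 0 genes by limma (21 at an unadjusted p under 0.05). Groups were pooled for the first test, and reads assigned to the wrong isoform would blur such differences. Positions held by all 4 libraries are absent here too. Whether their absence lowers the more covered isoform more than the other was not tested, so the direction of these differences stays open.

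The RPS2 coverage test and its ratios by library number, the bootstrap bounds of the list test and the test of length as the whole cause for glycolysis were written only after their results were seen. For HEK293T, 1 of 10 splits of the 6 libraries called as many genes as the real grouping, namely the real grouping itself, both for edited reads (653, highest other 0) and for editing per read (375, highest other 0), and 10 splits are too few for a share under 0.05.

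In CoCl2-treated MDA-MB-231 cells coverage fell for long and rose for short transcripts, which could come from shorter molecules in the CoCl2 libraries or from regulation of genes that differ in length. Between isoforms of the same gene the slope was -0.19 per doubling (95% interval -0.26 to -0.13; 1812 isoforms of 831 genes) against -0.52 between genes, so a length effect within genes was present but smaller, and the share due to the libraries stays open. For the hypoxia and glycolysis lists, the smaller ratio of the median without to with the trend was 0.834, and their medians without it were 0.36 (0.21 to 0.61) and 0.49 (0.13 to 0.77). camera called both without the trend (adjusted p = 0.000387 and 4.65e-05, or 0.331 each with an estimated correlation), while the ribosomal median went from 0.76 to -0.02. For glycolysis the lower bound, 0.129, lay above 0 but under 0.30, 50% of its value as measured. Such bounds rest on list members, which are not independent replicates, and with an estimated correlation the list was not called. Whether length was the whole cause, and how much it added, therefore stays open. The hypoxia list, of long transcripts, was not called as measured (median 0.08), so the removal of the trend does not test length as a cause of a rise there.

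Genes called for edited reads in MDA-MB-231 could owe their calls to positions left out because all 4 libraries held them. At positions not listed in 1 given library, averaged over the 4 choices of that library, the median ratio of the log2 change to the reported one was 0.872 (interquartile range 0.779 to 0.950), and 614 of 614 genes kept their direction. Every listed position was missing from at least 1 library, so the 4 sets reuse the reads behind the calls. The kept direction is therefore not independent support. Whether the absent positions shaped the calls stays open, since they were not seen.

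RPS2 rose most in editing per read in HEK293T under the naming rule, which could reflect reads of the construct's own RPS2 coding sequence. Its depth-matched coverage was 89.8, 73.0 and 366 in APOBEC1-only and 52.1, 79.4 and 204 in Ribo-STAMP, a ratio of means of 0.634. Ratios of single libraries ran from 0.142 to 2.80. Ratios of libraries with the same number were 0.580, 1.09 and 0.557 (geometric mean 0.706, 95% interval 0.278 to 1.79). Coverage was not higher in every Ribo-STAMP library, but both ranges reach past 1.2, the highest ratio set for excluding construct reads, which stay open.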
